A study of Caenorhabditis elegans with 2 samples.

How the data were processed

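Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans L4 larvae of mixed sex that carry a transgene encoding the homeobox protein CEH-62 with a GFP-FLAG tag at its C terminus. Per the labels, chromatin was fragmented by sonication and there were 2 biological replicates of this single condition. The study holds no other group, so no difference between groups was tested and no pairing of samples arose.

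Per the file inventories deposited with the samples, each replicate list holds peaks and background regions called from that replicate's alignments with 1 control. By the same inventories, a pooled list was called from both replicates' alignments with the same control. An optimal list was derived from the pooled list and both replicate lists by the irreproducible discovery rate (IDR), a method based on how well peak ranks hold up across replicates. The optimal list was exactly the strongest part of the pooled list, so an optimal peak need not rank high in both replicates. Each kind of list was deposited for the genome builds ce10 and ce11, which gave 8 lists. The aligner, the peak caller, the IDR threshold and the read numbers are not given in the sources used here, so the sequencing depth is unknown, and counts of reads behind a peak cannot be stated. The control itself was not analysed here.

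The deposited lists give a signal value for each entry, which is the authors' own peak-caller score on a scale that is not stated. One more column was read as the −log10 of a q-value, from the narrowPeak layout named in the deposited file inventories. The sources used here do not state the unit of that column for these lists, and every q-value rests on this reading. Signal values were used to describe, rank and filter entries within a list, to correlate matched entries of the replicate lists, and to set the pooled lists of the builds side by side. Ratios and correlations of signal depend on the unstated scale. Pooled and replicate signals are on different scales and were not compared with each other. Because both replicates were called against the same control, part of any overlap between them may come from it.

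Coordinates are those of ce11, counted from 1. The last entry on each chromosome ended at or before the chromosome's end in the WBcel235 reference, which is the same assembly, and gene models were taken from Ensembl release 115. Names of mitochondrial protein-coding genes came from RefSeq annotation of WBcel235 by position and biotype. The ce10 lists were used for counts, overlaps within the build and signal, and no coordinates were converted.

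Replicate overlap was the share of the 1000 strongest entries of replicate 1 that shared at least 1 bp with any of the 1000 strongest of replicate 2, against 100000 circular shifts within chromosomes (permutation test, one-sided, with 10000 shifts for the alternatives). Signal was correlated on the log2 scale across pooled entries with a summit within 150 bp in both replicate lists. A summit was assigned to a promoter when it lay between 1000 bp upstream and 200 bp downstream of the annotated start of a protein-coding gene. Optimal peaks were compared with all other pooled entries, which had passed the same calling steps, by Fisher's exact test (two-sided). For gene classes, genes with an optimal summit in the promoter window were compared with genes that had only other pooled summits in it, with Benjamini-Hochberg adjustment over 18 classes. These were homeobox genes, other transcription factors, ribosomal proteins, translation factors, histones, collagens and cuticle genes, neuropeptides and insulins, pan-neuronal, muscle, intestine, germline, pharynx, and hypodermis and molting genes, oxidative phosphorylation, heat shock, major sperm proteins, tRNA genes, and snRNA and snoRNA genes. TAATTA, a common homeodomain core, was searched within 100 bp of each summit, and TAAT was counted in the same windows against pooled entries drawn from the 100 closest in GC content (permutation test, 100000 draws, two-sided). Intervals on shares are exact Clopper-Pearson 95% intervals over peaks, and intervals on odds ratios are conditional 95% intervals. They cover counting error over peaks and not variation between worms.

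The classes, main tests, alternatives and the rule for named peaks were fixed before the data were examined. The tests under Other observations were added later, to weigh patterns seen in the main results. The rule took the 30 optimal peaks with the highest signal, the tagged gene, and up to 10 members of each class with an adjusted p under 0.05. Alternatives included other numbers of ranked entries, other overlap definitions, promoter windows and backgrounds, the ce10 lists, and lists made from a single replicate. Lists without mitochondrial DNA, the 90 strongest pooled entries and counts by distinct interval were added after the data were seen. Intervals listed with more than 1 summit were otherwise counted once per summit.

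The replicate overlap, the Pearson correlation, the gene classes, the promoter windows, the motif tests and the count of repeated words were tested on simulated data. The comparisons of chromosomes, of support by each replicate, of starts on both strands, of shifts along mitochondrial DNA and of windows at the tagged gene were not. With 80 of 1000 entries planted as shared, the overlap test recovered a mean of 78.5 above the shifted mean and called 50 of 50 runs, against 6% of runs with none planted. With 4 ribosomal genes planted among 37, the class test called the class in 100 of 100 runs. With TAATTA planted in 15 of 50 windows, the TAATTA test called 100% of runs and the TAAT count test 34%, and with none planted each called 6%. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.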

Results

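CEH-62, also known as R06F6.6, is a homeobox protein, and the experiment asked where its tagged form was found on chromatin in L4 larvae. The strongest entries in these lists lay on mitochondrial DNA, and the strongest nuclear peak lay upstream of cdc-48.1. Whether the mitochondrial entries reflect binding of CEH-62 could not be decided from these lists. Each of the 2 replicates was represented by a list of 30000 entries on ce11, which mixes peaks with background. The pooled list held 16733 entries and the optimal IDR list 50 peaks. All signal values below are the authors' peak-caller values, and they carry no error of their own. The median signal was 8.65 in replicate 1 and 8.09 in replicate 2. The q-values come from a column read as −log10 q by the usual order of columns, which the sources used here do not state for these lists, so they hold only if that reading is right. Read so, the smallest q-value was 0.227 in replicate 1, 0.0245 in replicate 2 and 0.155 in the pooled list. At q under 0.05 there were 0 entries in replicate 1, 922 in replicate 2 and 0 in the pooled and optimal lists.

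Mitochondrial DNA carried 23 of the 50 optimal peaks, or 46% (95% interval 31.8 to 60.7), and all 23 mitochondrial entries of the pooled list were optimal. A peak here is an entry with its own summit, and 2 mitochondrial intervals, at 2372 to 2802 and 3778 to 4169, are each listed with 2 summits. By distinct interval, mitochondrial DNA held 21 of 48, or 43.75% (95% interval 29.5 to 58.8). Their median signal was 942.7, which was 19.9 times the median of 47.4 at the nuclear optimal peaks. The strongest peak lay in the coding exon of CYTB, the cytochrome b gene of respiratory complex III, at position 4588 to 4940, with a pooled signal of 6245. It ranked 1 in replicate 1, with a signal of 2519, and 1 in replicate 2, with a signal of 3596. The next were both in the coding exon of ND5, a subunit gene of complex I. The first, at 12185 to 12537, had a pooled signal of 3211 and ranked 2 in both replicates, and the second, at 13013 to 13375, had a pooled signal of 2224 and ranked 3 in both. A peak in the coding exon of ND2 at 3501 to 3859 had a signal of 1746 and ranked 5 in replicate 1 and 4 in replicate 2. By position, 16 mitochondrial summits fell in coding exons, 5 in non-coding exons of rRNA or tRNA genes, 1 in the 3′ UTR of COX1 and 1 outside annotated genes, at 13658 to 13794. The remaining mitochondrial peaks had signals from 1375 down to 83.6, and their nearest protein-coding starts were those of ATP6, COX1, ND3, COX3, ND4, COX2, ND1, ND4L, ND2, CYTB and ND5. Across the 18 mitochondrial entries matched in both replicates, Spearman's rho of the signal was 0.624 and Pearson's r of log2 signal 0.70. These entries are not independent replicates.

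**Figure D1:**
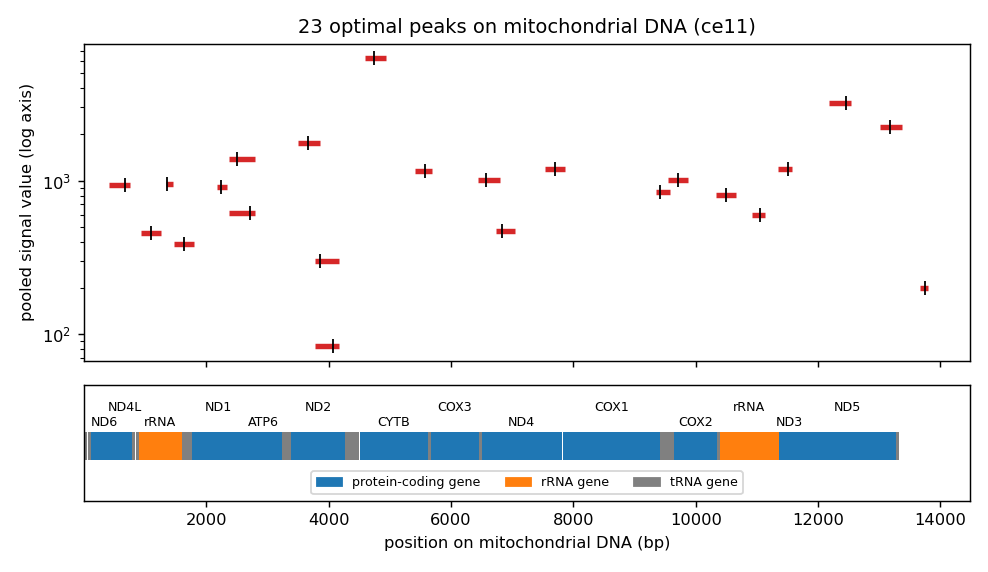
Optimal peaks on mitochondrial DNA. The upper panel plots each of the 23 peaks as a red bar from start to end (x axis, bp) at its pooled signal value (y axis, log scale), with a black tick at the summit, and the lower panel shows protein-coding, rRNA and tRNA genes. The highest bar, at 6245, lies in CYTB.

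The nuclear peaks numbered 27, with signals from 42.6 to 101. The strongest lay on chromosome II at 10563411 to 10563746, in intergenic sequence 172 bp upstream of the start of cdc-48.1, which encodes an AAA ATPase of the p97 family. Its signal was 101, and it ranked 21 in replicate 1 and 34 in replicate 2. The peak with a signal of 65.4, on chromosome II at 5844599 to 5844934, was intergenic and lay 98 bp upstream of sls-2.1, a gene for SL2 spliced leader RNA. Its nearest protein-coding start was that of ZK1248.17, and it ranked 24 in replicate 1 and 30 in replicate 2. An intergenic peak on chromosome III at 8043800 to 8044135, 519 bp upstream of K12H4.5, had a signal of 59.6 and ranks of 38 and 40. On chromosome X, a peak at 12363075 to 12363410, 1661 bp from the start of F19H6.5, had a signal of 58.0 and ranks of 78 and 35. Another on X, at 16056492 to 16056827 near T27A8.7, had a signal of 53.7 and ranked 32 in replicate 2 but 19892 in replicate 1. On chromosome IV, the peak at 654675 to 655010 lay 267 bp upstream of rpl-15, a ribosomal protein gene, with a signal of 53.0 and ranks of 360 and 54. The peak at 8431678 to 8432013 on IV lay in an intron of T26A8.4, with a signal of 51.9 and ranks of 28 and 176. Among the other 20 nuclear peaks, examples chosen after their values were seen include those upstream of tba-2 (alpha-tubulin, 152 bp), cox-5A (a cytochrome c oxidase subunit, 309 bp), npp-18 (a nuclear pore protein, 74 bp) and set-16 (a histone methyltransferase, 147 bp). Their signals were 47.5, 48.5, 43.8 and 43.7. They ranked 2490, 2422, 395 and 6005 in replicate 1, and 41, 37, 78 and 50 in replicate 2.

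The replicates overlapped at the mitochondrial sites and at part of the nuclear peaks, such as those at cdc-48.1, sls-2.1 and K12H4.5, and at little of the rest of their lists. On mitochondrial DNA overlap is likely from position alone, since entries of replicate 1 covered 35.8% of it and those of replicate 2 covered 53.3%. Of the 1000 strongest entries of replicate 1, 97 overlapped one of the 1000 strongest of replicate 2, or 9.7% (95% interval 7.94 to 11.7). The shifted lists gave a mean of 22.7 and at most 41 (permutation test, one-sided, p = 1e-05, the smallest the shifts can give). On nuclear chromosomes alone 82 of 1000 overlapped, which was 11.8 times the shifted mean of 6.96. Of the 50 optimal peaks, 50 overlapped one of the 1000 strongest entries of replicate 2, and 40 one of replicate 1. The 40 found in both made up 80% (95% interval 66.3 to 89.97) and comprised 21 of 23 mitochondrial and 19 of 27 nuclear peaks. The optimal list was itself derived from the pooled and both replicate lists, so these shares are not an independent test of support. By distinct interval 38 of 48 were found in both, among them 19 of the 21 on mitochondrial DNA. No shifted value was computed for the mitochondrial counts, so they alone are no evidence that the replicates agree there. Nuclear optimal peaks had a median rank of 153 in replicate 1 and 54 in replicate 2. The cox-5A, tba-2, set-16, hsr-9, tasp-1, W02H3.3, xol-1 and T27A8.7 peaks (nearest protein-coding start) were the 8 outside the 1000 strongest of replicate 1.

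**Figure D2:**
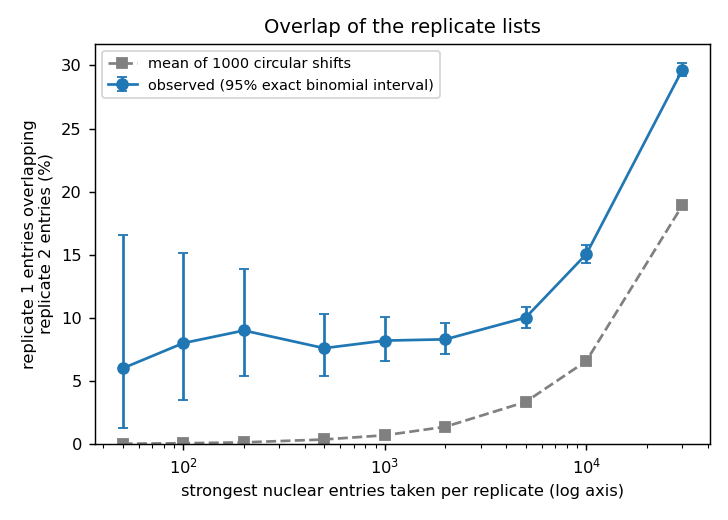
Overlap of the nuclear entries of the replicates. The x axis (log scale) gives how many of the strongest entries were taken from each list, and the y axis the percent of replicate 1 entries that overlapped replicate 2 entries. Circles show observed shares with 95% exact intervals and squares the mean of 1000 shifts. The observed share stayed between 6% and 9% up to 2000 entries and reached 29.7% with the full lists, against 18.9% in the shifts.

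Across the 4773 of 16733 pooled entries with a summit in both replicate lists, Spearman's rho of the signal was 0.0269 and Pearson's r of log2 signal 0.42. The correlation is across peaks, which are not independent replicates. Without mitochondrial DNA, Pearson's r was 0.07. Among the 1000 strongest pooled nuclear entries rho was -0.328, and among the 26 matched nuclear optimal peaks it was -0.408. These entries were selected by their pooled signal, and for nuclear entries matched directly between the replicate lists, without the pooled list, rho was 0.0979 over 5178 entries.

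**Figure D3:**
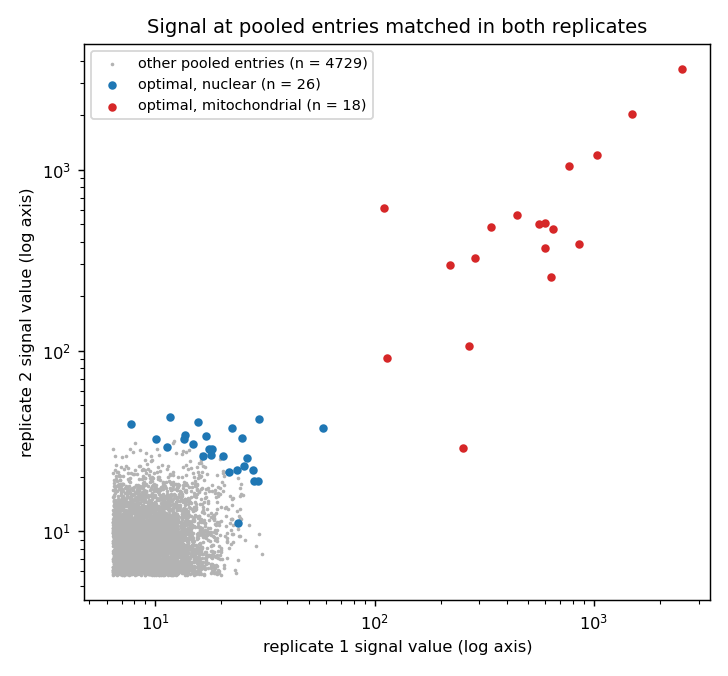
Signal of pooled entries matched in both replicates. Each point is an entry, with its replicate 1 signal on the x axis and its replicate 2 signal on the y axis (both log scales). The 18 mitochondrial optimal peaks (red) spread along the diagonal up to 2519 and 3596, the 26 nuclear optimal peaks (blue) sit at the edge of the cloud, and the other entries (grey) show no visible slope.

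Promoters of protein-coding genes held most of the optimal peaks. On nuclear chromosomes 19 of 27 summits lay in a promoter window, or 70.4% (95% interval 49.8 to 86.2), against 26.6% of the other pooled entries (odds ratio 6.54, 95% interval 2.73 to 17.3, Fisher's exact test, two-sided, p = 2.69e-06). With mitochondrial peaks included, 39 of 50 summits did so, or 78% (odds ratio 9.77, 95% interval 4.90 to 21.2, Fisher's exact test, p = 5.94e-14). The rise over the nuclear value is no evidence of enrichment, because on mitochondrial DNA 77.1% of all positions lie in such a window and the other pooled entries are all nuclear. The median distance of a nuclear optimal summit to the nearest protein-coding start was 235 bp, against 1471 bp for the other nuclear entries. In 7 of 27 nuclear peaks the summit lay in the windows of genes on both strands, as between rps-19 and hsr-9, eef-1A.1 and rfc-4, drr-2 and set-16, and tlf-1 and cdk-8. This was 25.9%, against 3.31% of the other entries (odds ratio 10.2, Fisher's exact test, two-sided, p = 2.26e-05, a comparison chosen after the data were seen). Such a summit is in a promoter window by definition, so part of this ratio restates the promoter enrichment. Among nuclear summits in a promoter window, 7 of 19 optimal and 553 of 4443 other summits were of this kind, which was not tested. The promoter share fell with rank, from 52.1% at nuclear ranks 28 to 100 to 37.1% at 301 to 1000 and 24.2% beyond 10000.

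**Figure D4:**
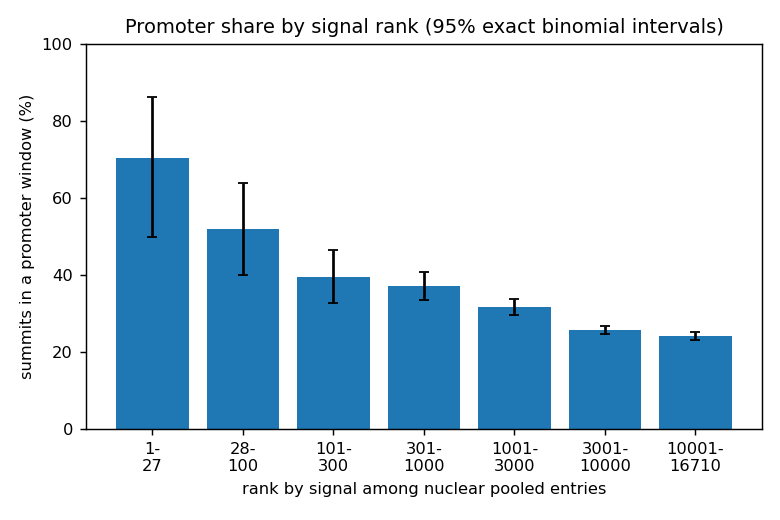
Promoter share by signal rank. Bars give the percent of nuclear pooled entries with a summit in a protein-coding promoter window (y axis) in 7 rank ranges (x axis), with 95% exact intervals. The share goes from 70.4% in the 27 strongest to 24.2% in the weakest range.

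Of the 18 gene classes, 3 passed an adjusted p of 0.05 beside optimal peaks, and on nuclear chromosomes alone 2 did, ribosomal protein genes (odds ratio 15.96, adjusted p = 0.0124) and snRNA and snoRNA genes (odds ratio 13.2, adjusted p = 0.00141, both by Fisher's exact test). Ribosomal protein genes made up 3 of 37 protein-coding genes with an optimal summit in their promoter (rpl-15, rps-19 and rpl-20), against 38 of 4688 background genes (odds ratio 10.8, 95% interval 2.03 to 36.7, Fisher's exact test, adjusted p = 0.0230). The summits beside rps-19 and rpl-20 lay nearer the starts of hsr-9 (116 bp) and Y17G9B.5 (126 bp). The peak shared by rps-19 and hsr-9 ranked 1441 in replicate 1. The class of snRNA and snoRNA genes had 5 members beside peaks, namely sls-2.1 and the snoRNA genes C06A1.9, T27A8.8, K11H12.12 and K11H12.13 (odds ratio 6.47, 95% interval 2.00 to 16.3, Fisher's exact test, adjusted p = 0.0140). K11H12.12 and K11H12.13 lie within rpl-15 and share its peak, so they are not independent of it. The test counted that peak once for each of these genes, so the p-values of the class overstate the evidence. T27A8.8 lies 714 bp from the summit of the peak near T27A8.7, which ranked 19892 in replicate 1. C06A1.9 shares the cdc-48.1 peak, whose summit lay 515 bp upstream of C06A1.9 but 172 bp upstream of cdc-48.1. Of tRNA genes, 21 were beside peaks (odds ratio 24.4, 95% interval 13.6 to 42.3, Fisher's exact test, adjusted p = 8.1e-19). This value is no evidence of enrichment, because no mitochondrial entry was left outside the optimal list and so no mitochondrial gene could enter the background. Of the 21 genes 20 are mitochondrial and share 9 peaks as their strongest, the highest signals being beside WBGene00014465, WBGene00014473, WBGene00014461, WBGene00014462, WBGene00014463, WBGene00014464, WBGene00014458, WBGene00014459, WBGene00014460 and WBGene00014466. On nuclear chromosomes only WBGene00022938, on X, was beside a peak, and no over-representation was detected there with 1 gene (odds ratio 1.58, 95% interval 0.0388 to 9.49, Fisher's exact test, adjusted p = 1). The 50 strongest entries of 1 replicate were also used in place of the optimal list. The ribosomal genes beside them were rpl-35 and rps-19 without replicate 1, and rpl-13 without replicate 2. They shared no gene, and rpl-15 and rpl-20 were in neither, so the call does not rest on the same genes in each replicate. The ribosomal class had 2 genes and an odds ratio of 9.19 without replicate 1 (Fisher's exact test, adjusted p = 0.140). Without replicate 2 it had 1 gene and an odds ratio of 7.21 (Fisher's exact test, adjusted p = 0.821). The snRNA and snoRNA class had 6 genes and 8.31 (adjusted p = 0.00137), and 2 genes and 3.30 (adjusted p = 0.821, both by Fisher's exact test). The narrower promoter window left the snRNA and snoRNA class at an adjusted p of 0.458.

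Homeobox genes had 0 of 37 beside optimal peaks, against 13 of 4688 in the background (adjusted p = 1), and other transcription factors 0 against 102 (adjusted p = 1, both by Fisher's exact test). Translation factors had 1, eef-1A.1 (adjusted p = 0.397), oxidative phosphorylation 1, cox-5A (adjusted p = 0.241), and the heat shock class 1, hsr-9 (adjusted p = 0.272), which the class took in by its symbol (all by Fisher's exact test). The oxidative phosphorylation class did not take in the mitochondrial genes beside optimal peaks, such as CYTB and ND5, which also encode subunits of respiratory complexes. Its count of 1 therefore leaves those genes out. The tissue classes of neuropeptides and insulins, pan-neuronal, muscle, intestine, germline, pharynx, collagens and cuticle, and hypodermis and molting genes had 0, as did histones and major sperm proteins, each with an adjusted p of 1 by Fisher's exact test. With 37 genes beside peaks the 95% upper limit of the odds ratio was 43.2 for homeobox genes and 4.80 for other transcription factors, so a moderate enrichment was not detectable at this list size. Some of the 37 are mitochondrial, while the background genes are all nuclear. On nuclear chromosomes alone, with 26 genes beside peaks, the upper limits were 62.6 and 6.97.

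The homeodomain core TAATTA was present within 100 bp of 9 of 50 optimal summits, or 18% (95% interval 8.58 to 31.4), and of 11.4% of the other pooled entries (odds ratio 1.70, 95% interval 0.726 to 3.56, Fisher's exact test, two-sided, p = 0.176). The TAAT count was 4.60 per window, against 3.10 in pooled entries matched on GC content (permutation test, two-sided, p = 1e-05, the smallest the draws can give). Both comparisons set 23 mitochondrial and 27 nuclear peaks against nuclear entries only, since no mitochondrial entry was left outside the optimal list, so they compare mitochondrial with nuclear sequence in part. The excess was not found at the nuclear peaks alone. At the 27 nuclear peaks the TAAT count was 1.89, against 2.11 in matched entries (permutation p = 0.509), and TAATTA was present at 2 of 27, namely the cox-5A peak and a peak in C30E1.9, a non-coding gene on X (odds ratio 0.620, 95% interval 0.0711 to 2.49, Fisher's exact test, p = 0.763). The TAATTA test was not matched on GC content, which was 38.1% at these nuclear peaks and 32.3% at the other entries. Its odds ratio may therefore reflect base composition in part. At the 23 mitochondrial summits the TAAT count was 7.83, against a mean of 7.39 with an SD of 0.703 over all circular shifts of those summits along the mitochondrial genome.

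Chromosome X held 6 of the 27 nuclear optimal peaks, or 22.2%, against 14.5% of the other nuclear entries (odds ratio 1.68, 95% interval 0.554 to 4.31, Fisher's exact test, two-sided, p = 0.270). The X peaks were those nearest F19H6.5, T27A8.7, W02H3.3, F09E10.1, C30E1.4 and xol-1. With the 50 strongest entries of replicate 1 alone, X held 1 of 30 nuclear entries (odds ratio 0.183, Fisher's exact test, p = 0.0756). Chromosome V held 0 of 27, against 18.1% of the other entries (Fisher's exact test, p = 0.00955, adjusted p = 0.115 over all chromosomes of both builds, a comparison chosen after the data were seen). On ce10, V held 8 of 69.

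The tagged gene, ceh-62 (WBGene00011069), lies on chromosome II at 10805737 to 10808611 on the plus strand. Within 20000 bp of it there were 2 entries of replicate 1, 0 of replicate 2, 1 of the pooled list and 0 optimal peaks. Windows of the same width on the chromosome held a mean of 11.97, 12.2 and 6.62 entries of the first 3 lists. The counts at ceh-62 were at percentiles 0.512, 0.0689 and 3.66 of those windows. No summit of either replicate list fell between 10772673 and 10827171, a stretch of 54.5 kb. The GC content of the window, 35.7%, was at percentile 41.9. Within 50000 bp, the pooled list held 8 entries, at percentile 9.97, and the strongest had a signal of 24.9 and a rank of 971.

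**Figure D5:**
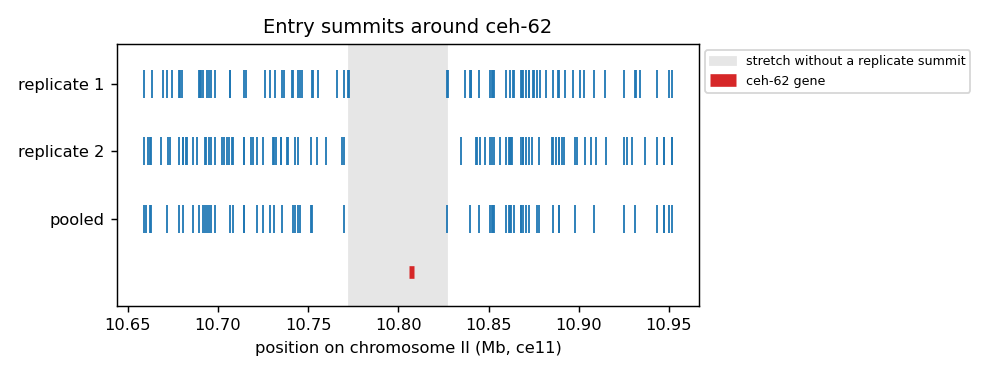
Entries around ceh-62. Ticks mark entry summits of the replicate and pooled lists along chromosome II (x axis, Mb), the red bar the ceh-62 gene, and the shaded area the 54.5 kb without a summit of either replicate.

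The number of optimal peaks differed between builds, with 50 on ce11 and 90 on ce10, while the signals were close. The pooled list held 16810 entries on ce10, and the highest pooled signal was 6208 there and 6245 on ce11. On each build the optimal list was exactly the strongest part of the pooled list, down to a signal of 42.6 on ce11 and 37.1 on ce10. On ce11, 90 pooled entries had a signal at or above that of the weakest optimal peak on ce10. Mitochondrial DNA held 21 of the 90 peaks on ce10. On that build 57 of 90 optimal peaks overlapped the 1000 strongest entries of both replicates.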

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

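The settings without mitochondrial DNA, with the 90 strongest pooled entries and by distinct interval were chosen after the data were seen. The overlap of the replicates stayed above chance in all 7 alternatives (5.5% to 10.8%). The promoter enrichment stayed past its threshold in all 10 (odds ratios 3.85 to 14.4). In the 3 on nuclear chromosomes the odds ratios were 3.85 to 8.99. The others included mitochondrial peaks, whose promoter share is no evidence of enrichment. Both settings without a replicate (3.93 to 8.30) were among them, so whether the nuclear enrichment holds without a replicate was not tested. Spearman's rho moved to 0.0554 with summits within 50 bp, -0.236 in the strongest 1000 pooled entries, -0.328 in the strongest 1000 pooled nuclear entries and 0.0979 when nuclear entries were matched directly. The share of optimal peaks in both replicates moved to 66% with a 50% reciprocal overlap and 63.3% on ce10. The X odds ratio was 0 in the 25 strongest peaks, where only 2 were nuclear, and 0.183 to 1.89 without a replicate. The number of called gene classes was 1 to 2 without a replicate and 5 with the window of 2000 bp upstream to 500 bp downstream, against 3. Leaving out tRNA genes, whose call rests on mitochondrial DNA, the counts were 0 to 1 without a replicate, 4 with that window and 1 with the narrower one, against 2. The TAATTA odds ratio passed the threshold in the 25 strongest peaks (3.02), mostly mitochondrial, and with 200 bp around the summit (2.46), and was 0.620 on nuclear chromosomes. The TAAT difference from matched entries turned negative without mitochondrial DNA, at -0.220, and at -0.169 for the nuclear part of the 90 strongest pooled entries, but was 0.771 for all 90. The percentile of the pooled count at ceh-62 was 9.97 with 50000 bp and 35.1 for the strongest 1000 entries, of which most windows held 0. The number of optimal peaks was 90 on ce10 and 27 on nuclear chromosomes. Except where stated, the cause was not tested. Over all results and alternatives, 66 of 92 kept direction and side of the threshold or stayed within the spread. Read depth is unknown, so its part in the difference between the replicates cannot be judged.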

Other observations

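The tests in this section were added to weigh patterns already seen in the results above. Those of mitochondrial coverage, of the evenness of the mitochondrial signal and of TAATTA in the ribosomal protein gene peaks were chosen only after their own results were seen. Among genes first reached at pooled ranks 51 to 1000, all of them nuclear, ribosomal protein genes and tRNA genes were over-represented at an adjusted p under 0.05 over the 18 classes. Ribosomal protein genes made up 15 of 460 protein-coding genes, against 23 of 4228 at lower ranks (adjusted p = 1.99e-05), and tRNA genes 29 of 947 genes of any type, against 171 of 10635 (odds ratio 1.93, 95% interval 1.25 to 2.897, adjusted p = 0.0219, both by Fisher's exact test, two-sided). By the same exact test, translation factors, 5 of 460 against 12 of 4228 (adjusted p = 0.122), and snRNA and snoRNA genes, 18 of 947 against 118 of 10635 (adjusted p = 0.176), did not pass. Homeobox genes had 0 of 460 there, against 13 of 4228.

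On ce11, 7 stretches of at least 40000 bp had no summit of either replicate, and in 6 of them 49.6% to 98.2% of 31-base words occur more than once in the reference genome. In the stretch at ceh-62, which spans 14 protein-coding genes from mpz-1 to mix-1, the share was 0.545%, which argues against repeated sequence there. A sparse chromosome region is argued against too, since the median count in windows 50 kb to 1 Mb away was 100% of the chromosome median. The stretch was the longest of 8608 on chromosome II and takes up 0.357% of it, which describes the pattern and supports no cause. Extra copies of the tagged locus in the control cannot be told apart from a filter by the authors or another feature of the region, because the control and its strain were not analysed here.

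The mitochondrial peaks were weighed in the same way. The strongest mitochondrial signal was 4.35 times the median in replicate 1 and 9.36 times in replicate 2. Both ratios were above the bound set for an even excess of fragments along the molecule. The strongest entries also overlapped, at 4613 to 4927 in replicate 1 and 4439 to 4941 in replicate 2. The scale of the signal is not stated and the control is shared, however, so an even excess cannot be told apart from other sources. The same holds for high copy number of mitochondrial DNA, since the lists fell on different sides of the bound of 50% set for it, with 44.5% of the molecule covered by the optimal peaks, 35.8% by replicate 1 entries and 53.3% by replicate 2 entries. Binding at the homeodomain core stays open as well, because 7 of 23 summits lay near TAATTA against a mean of 7.16 with an SD of 1.97 over shifts, and 64.9% of shifts gave as many. No biological explanation beyond that was tested.

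Of the 3 nuclear peaks beside ribosomal protein genes, 0 held TAATTA in their interval, which argues against recruitment through an exact TAATTA there. It shows no depletion, since only 11.4% of the other pooled entries had TAATTA within 100 bp of the summit, and 21.3% within 200 bp. The intervals are 336 bp wide, which lies between the widths of these windows. The shorter TAAT was present in all 3 intervals, with 3, 1 and 5 copies. TAAT is common, with a mean count of 2.91 within 100 bp of the other pooled summits and 5.77 within 200 bp. Its presence in all 3 is therefore no evidence of recruitment through TAAT. Over the 27 nuclear peaks, recruitment through the homeodomain core cannot be told apart from its absence, since the odds ratio of TAATTA was 0.620 with an interval of 0.0711 to 2.49. That ratio was also not matched on GC content. The ribosomal class was over-represented at pooled ranks 51 to 1000 as well (odds ratio 6.16, 95% interval 2.97 to 12.4, Fisher's exact test, two-sided, p = 1.11e-06). Open chromatin at highly transcribed promoters would give this, and so would weaker sites of CEH-62, so the test does not separate them and both stay open. Transcription and lists of other tagged proteins were not analysed here.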
